A study of Rattus norvegicus with 19 samples.

How the data were processed

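Gene expression was measured in 19 samples of rat cells (Sprague-Dawley strain) on Affymetrix arrays, which read each transcript with sets of short probes. The labels name 4 stages of the Leydig cell, the testosterone-producing cell of the testis: stem Leydig cells (n = 5), progenitor Leydig cells (n = 3), immature Leydig cells (n = 4) and adult Leydig cells (n = 4). A further group holds bone stem cells (n = 3). Ages, culture conditions and the way the cells were isolated are not given in the sources used here. Total RNA was extracted with Trizol and column purification, and biotin-labelled cRNA was made from 6 ug, per the labels' protocols.

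The deposited values are intensities on a linear scale, 1 signal per probe set and array, made with MAS5 in GCOS per the submitters' processing notes. No versions are given there. The authors' table was already scaled: the 2% trimmed mean of the signal was 100 on each array. No detection calls were used here, so low signals have no tested floor. The median signal of an array ranged from 18.9 to 36.6, and 29.1% to 47.3% of probe sets lay under a signal of 16. The number of arrays per group limits the precision.

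The table holds 31099 probe sets, and the 57 control probe sets were left out of the tests, which leaves 31042. In the platform annotation used, 20826 probe sets have 1 gene symbol, 436 have several and 9780 have none. Symbols were looked up by gene ID in a RefSeq gene table, which held 20764 of the 20826, and 0 symbols needed updating. A gene with several probe sets was represented by the one with the highest mean over all arrays, which gave 14217 genes. No coordinates are printed, since no genome build is named for the array table.

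Signals were transformed to log2(signal + 16), so that a log2 change understates the fold of a dim gene. All 19 arrays entered one linear model with 5 group means in limma 3.58.1 (R 4.3.3), with moderated statistics and an intensity trend. Differences were tested in both directions with Benjamini-Hochberg adjustment over the 31042 probe sets, and a probe set was called at an adjusted p under 0.05. Unless another fit is named beside it, the adjusted p of a gene comes from this model, and each log2 change is given with its standard error (SE). A moderated F-test over the 3 steps counted probe sets that differed among the 4 Leydig stages. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.

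The labels do not say whether samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

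Before the data were examined, 19 gene lists were fixed, 13 of pathways and 6 of markers of cell types. Of their 463 symbols, 404 had a named probe set. The pathway lists cover testosterone synthesis, androgen and glucocorticoid metabolism, cholesterol synthesis and uptake, Leydig hormone receptors and regulators, stem and mesenchymal precursors, the cell cycle, extracellular matrix, antioxidant and glutathione enzymes, the insulin-like growth factor axis, Wnt and Notch signalling, gonad and Hox transcription factors, osteoblast, cartilage and fat genes, and immediate early and heat shock genes. The marker lists cover germ cells, Sertoli cells, leukocytes, smooth muscle, endothelium, and erythroid and bone marrow cells. Each list was compared with all other genes by limma's camera test with a preset correlation of 0.01, adjusted over the 19 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Fry tests whether the genes of a list move one way on balance, and its mixed form whether they change in either direction. Neither compares a list with other genes.

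The rule for named genes was fixed before the data were examined as well. It took, per comparison, the 4 largest rises and the 4 largest falls among called genes whose groups did not overlap and whose brighter group lay at or above the median probe set. It added the 2 called members with the smallest adjusted p from each pathway list and 1 from each marker list. Star, Cyp11a1, Cyp17a1, Hsd17b3, Lhcgr and Insl3 in the Leydig comparisons, and Pdgfra in all 5, were named whatever their result. Symbols that only stand for a predicted gene were passed over. A gene the rule names in one comparison may be given in another. No other probe set of a named gene was called in the opposite direction.

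The alternatives were quantile normalization, median centring of each array, a pseudocount of 1 or 64, leaving out the lowest 40% of probe sets, no intensity trend, array quality weights, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, the mean of all probe sets of a gene, and leaving out each array in turn. A further 2 were chosen after seeing the data, one that leaves out 2 arrays standing apart and one that averages the 2 closest pairs of arrays.

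The model was tested on simulated data made from the real probe set means and residual spread of the 31042 probe sets, with 100 probe sets changed 2-fold and 100 changed 4-fold in each comparison. It recovered 87 of the 2-fold changes for progenitor against stem, 65 for immature against progenitor, 78 for adult against immature, 82 for adult against stem and 79 for stem against bone stem. Of the 4-fold changes it recovered at least 96 in each comparison, and unchanged probe sets called by chance numbered 6 to 14. In a simulation over 14217 genes for progenitor against stem, the camera test called the 1 list of 19 that had been raised by a log2 change of 1, and 0 of the others. The simulated genes varied independently of each other, while the estimated correlation within the real lists was up to 0.533. So this run does not show how often the test would call an unchanged list in the real data.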

Results

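The arrays fell first into stem cells and later Leydig cells. The first principal component, with 57.4% of the variance, set the 5 stem Leydig and 3 bone stem arrays apart from the 11 progenitor, immature and adult arrays. The second, with 13.8%, ordered the later arrays from progenitor to adult, and the third, with 10.6%, separated stem Leydig from bone stem arrays. Among the 4 Leydig stages, 15734 of 31042 probe sets (50.7%) differed in the F-test. Of these, 5433 were highest in stem, 3769 in progenitor, 2392 in immature and 4140 in adult cells.

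Some arrays stood apart. Immature replicate 4 correlated more with the progenitor arrays (mean r = 0.972 across probe sets) than with the other immature arrays (0.959), and its second component score of 51.7 lay among those of the progenitors. Progenitor replicate 3 had the highest ratio of 3' to 5' signal for beta-actin (6.346, against 1.026 to 2.951 on the other arrays). For beta-actin this ratio was 2.384 to 2.951 on the bone stem arrays and 1.026 to 1.836 on the stem Leydig arrays. For Gapdh it was 1.303 to 1.334 and 1.06 to 1.132. So a difference in RNA quality cannot be told apart from a difference between these 2 kinds of cell. The bioB hybridization control was at 19.2 on immature replicate 4 and at 150.6 to 2301.8 on the other arrays. Bone stem replicates 2 and 3, with a median absolute log2 difference of 0.068 over 5243 bright probe sets, and immature replicates 2 and 3, with 0.082, differed less than the other 26 pairs within groups (0.106 to 0.355). Whether these are repeat arrays of 1 RNA was not tested, so each was counted as a replicate, and counts with each pair averaged are given where they differ.

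**Figure D1:**
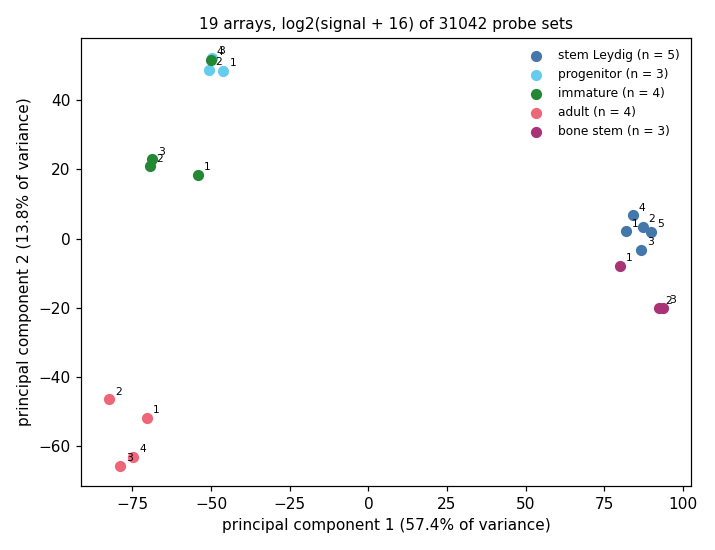
Principal component scores of the 19 arrays, component 1 (57.4% of variance) against component 2 (13.8%), from log2(signal + 16) of 31042 probe sets. Colours are groups and small numbers are replicates; immature replicate 4 sits among the 3 progenitor arrays.

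The first step of the lineage set progenitor against stem Leydig cells. Isolation and culture are not given, so a difference in these cannot be told apart from a difference of stage. This holds for the later steps too. Several genes of steroid synthesis and hormone response rose steeply. Cyp17a1, which encodes the enzyme that turns progestins into androgens, went from a signal of 1.09 ± 0.55 (SD, n = 5) in stem to 5130 ± 1390 (SD, n = 3) in progenitor cells, a log2 change of 8.19 ± 0.23 (adjusted p = 5.53e-16). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, rose by 6.19 ± 0.17, Hsd3b1 by 7.09 ± 0.31, the luteinizing hormone receptor gene Lhcgr by 6.09 ± 0.14 and the Leydig cell hormone gene Insl3 by 6.83 ± 0.26. Hsd17b3, the enzyme that makes testosterone from androstenedione, rose less, by 1.15 ± 0.22, to a signal of 52.5 ± 20.1. Star, the protein that brings cholesterol into mitochondria, was already at 740 ± 480 in stem cells, with single arrays from 242.9 to 1445.5, and its difference of 0.64 ± 0.64 was within the spread (adjusted p = 0.481).

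Of the 11 measured members of the testosterone synthesis list, 8 rose and 1, the mitochondrial membrane protein gene Tspo, fell (log2 change -1.20 ± 0.25), the same counts as adjusted over the list alone. The list rose against other genes (camera adjusted p = 8.3e-05, and adjusted p = 0.16 with an estimated correlation). Among Leydig receptors and regulators 13 of 16 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.16 with an estimated correlation). They include the steroidogenic regulator Nr5a1, at 77.4 ± 10.7 in stem and 767 ± 71.1 in progenitor cells. In cholesterol synthesis and uptake 10 of 19 rose and 0 fell (11 and 0 adjusted over the list alone), with Dhcr7 at 3.22 ± 0.16 and Stard4 at 2.02 ± 0.19. This list passed camera (adjusted p = 0.025) but not with an estimated correlation (adjusted p = 0.32). It did not pass without progenitor replicate 2 (adjusted p = 0.069), without stem replicate 1 (0.054) or with all probe sets of a gene averaged (0.064). Cell cycle genes rose in 30 of 38 cases and fell in 1, with the same counts adjusted over the list alone, at a median log2 change of 0.95 (camera adjusted p = 4.7e-06, and adjusted p = 0.25 with an estimated correlation). The mitotic motor gene Kif20a rose by 1.74 ± 0.14 and the spindle protein gene Nusap1 by 1.70 ± 0.20.

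Matrix and contractile genes fell. Tnc, which encodes the matrix protein tenascin C, fell from 1420 ± 207 to 3.78 ± 1.27 (log2 change -6.18 ± 0.14, adjusted p = 4.32e-17). Il1rl1 (-5.94 ± 0.19), the smooth muscle actin gene Actg2 (-5.80 ± 0.27), the bone morphogenetic protein antagonist gene Grem1 (-5.78 ± 0.17) and the collagen gene Col12a1 (-4.68 ± 0.16) also fell. In the extracellular matrix list 18 of 33 fell and 4 rose (18 and 5 adjusted over the list alone; camera adjusted p = 2.7e-05, and adjusted p = 0.25 with an estimated correlation). Of the 14 smooth muscle markers, 12 fell and 0 rose, as adjusted over the list alone (median -1.75; camera adjusted p = 5.2e-07, and adjusted p = 0.16 with an estimated correlation).

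Precursor markers went both ways. Of 25, 14 fell, with Thy1 going from 2040 ± 288 to 97.5 ± 32.6, and 8 rose, among them the hedgehog pathway gene Gli1 (3.98 ± 0.26) and the receptor gene Pdgfra (778 ± 195 to 1950 ± 261, log2 change 1.35 ± 0.20). The counts adjusted over the list alone were equal. The list fell by camera (adjusted p = 0.024, and adjusted p = 0.25 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.074), median centring (0.12) or without the lowest 40% of probe sets (0.071). The insulin-like growth factor binding protein genes Igfbp2 (5.60 ± 0.32) and Igfbp5 (5.01 ± 0.27) rose strongly. That growth factor list, with 7 of 15 risen and 3 fallen (8 and 3 adjusted over the list alone), did not pass camera (adjusted p = 0.065), but did with quantile normalization (0.039), median centring (0.024), a pseudocount of 64 (0.049) and without progenitor replicate 1 or stem replicate 1 (0.042 each).

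Markers of other cell types moved with these groups. Leukocyte markers rose in 17 of 24 cases and fell in 1 (18 and 1 adjusted over the list alone; median 2.03; camera adjusted p = 1.4e-06, and adjusted p = 0.25 with an estimated correlation). Laptm5 went from 8.44 ± 4.61 to 774 ± 113. Endothelial markers rose in 11 of 14 and fell in 1, as adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.25 with an estimated correlation). Erythroid and bone marrow markers rose in 10 of 12 and fell in 0, as adjusted over the list alone (camera adjusted p = 7.3e-05, and adjusted p = 0.16 with an estimated correlation). The beta-globin gene Hbb, at 4150 ± 925 in progenitor and 2.98 ± 0.835 in stem cells, rose by 7.75 ± 0.28. The seminal vesicle protein gene Svs5, which is in none of the marker lists, rose by 7.12 ± 0.18. Sertoli cell markers rose in 7 of 13 cases and fell in 1, as adjusted over the list alone, with Cldn11 at 3.85 ± 0.25, but the list did not pass camera (adjusted p = 0.065). Wnt and Notch genes went both ways, with 7 of 28 risen and 8 fallen, as adjusted over the list alone (camera adjusted p = 0.31); Sfrp1 rose by 3.03 ± 0.29 and Dkk3 fell by 3.75 on the log2 scale.

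In all, 6823 probe sets were higher and 4562 lower in progenitor cells (36.7% of those tested), 2461 and 1918 of them by 2-fold or more. The direction of the sum depends on scaling: 59.9% of called probe sets were higher as deposited, 49.2% after quantile normalization and 34.3% after median centring, which moved the median of all probe sets by -0.23. No named gene or list that was called changed direction under either scaling.

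**Figure D2:**
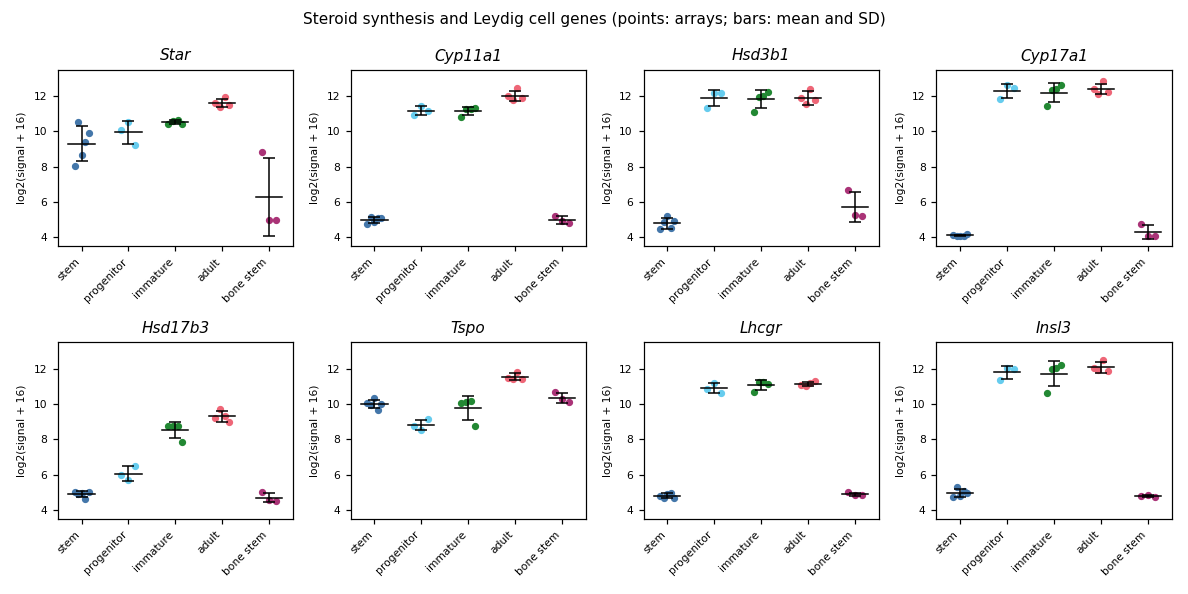
Signal of 8 genes of steroid synthesis and Leydig cell identity in each array, as log2(signal + 16) on the vertical axis, by group; points are arrays, bars the mean and SD. Cyp11a1, Hsd3b1, Cyp17a1, Lhcgr and Insl3 step up between stem and progenitor cells, while Hsd17b3 climbs over the 3 steps.

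The second step, immature against progenitor cells, was small. The testosterone enzyme gene Hsd17b3 rose from 52.5 ± 20.1 (SD, n = 3) to 366 ± 98.6 (SD, n = 4), a log2 change of 2.48 ± 0.23 (adjusted p = 1.46e-05). The cytochrome P450 gene Cyp4f4 rose by 2.91 ± 0.30 and Poteml2 by 2.29 ± 0.27. Hsd11b1, which interconverts active and inactive glucocorticoids, rose from 661 ± 37.2 to 1840 ± 284, and the gap junction gene Gja1 from 982 ± 193 to 2010 ± 329. Cyp11a1 (log2 change -0.01 ± 0.17), Cyp17a1 (-0.09 ± 0.24), Insl3 (-0.07 ± 0.27), Lhcgr (0.20 ± 0.15), Star (0.58 ± 0.67) and Pdgfra (0.07 ± 0.21) did not pass the test.

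Sfn (-2.29 ± 0.28), the pancreatic-type carboxypeptidase gene Cpa1 (-2.72 ± 0.48), Cldn5 (-2.27 ± 0.52) and Stc1 (-2.11 ± 0.44) fell. Cell cycle genes fell as a list (median -0.45; camera adjusted p = 2.5e-13, and adjusted p = 0.13 with an estimated correlation) although only 3 of 38 passed the test singly, 10 when adjusted over the list alone. Kif20a went from 329 ± 36.1 to 181 ± 25.8. Cholesterol synthesis fell as well (2 of 19, or 4 adjusted over the list alone; median -0.31; camera adjusted p = 2.1e-06, and adjusted p = 0.13 with an estimated correlation), with Idi1 at -1.19 ± 0.24 and Sqle at -0.72 ± 0.15. Antioxidant enzymes rose in 3 of 33 cases (6 risen and 1 fallen adjusted over the list alone), including catalase, Cat (0.77 ± 0.18). Cat no longer passed with the replicate number as a block. The antioxidant list passed camera (adjusted p = 0.0038) but not with an estimated correlation (adjusted p = 0.50) nor without progenitor replicate 3 (0.18). In the matrix list 0 of 33 passed the test singly, and 2 fell when adjusted over the list alone (median -0.24; camera adjusted p = 0.0027, and adjusted p = 0.73 with an estimated correlation).

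Germ cell markers rose in 7 of 21 cases and fell in 0 (14 and 1 adjusted over the list alone; median 0.73; camera adjusted p = 3.2e-09, and adjusted p = 0.13 with an estimated correlation). Prm1, a protamine that packs sperm DNA, went from 46.1 ± 71.6 (128.7 in progenitor replicate 3, 0.9 and 8.6 in the others) to 270 ± 112. Endothelial markers fell in 3 of 14 (9 adjusted over the list alone; median -0.84; camera adjusted p = 5.1e-08, and adjusted p = 0.13 with an estimated correlation). Immediate early and heat shock genes were lower as a list, with 0 of 21 past the test singly or adjusted over the list alone (median -0.20; camera adjusted p = 0.049, and adjusted p = 0.73 with an estimated correlation). Immature replicate 4 had the highest list mean of its group, 9.41 against 8.40 to 8.46. Erythroid and bone marrow markers fell as a list (0 of 12 singly; 1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.003, and adjusted p = 0.31 with an estimated correlation), a call lost without progenitor replicate 3 (adjusted p = 0.059) and without the lowest 40% of probe sets (0.34).

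This step called 272 probe sets higher and 132 lower, 404 in all, 189 of them by 2-fold or more. The count depends on single arrays. It was 1304 without immature replicate 4. It was 229 without progenitor replicate 1, 147 without progenitor replicate 2, 204 without immature replicate 1, 168 without immature replicate 2 and 202 without immature replicate 3. It was 1194 with progenitor replicate 3 and immature replicate 4 both left out, 157 with the closest pairs averaged, 226 with a pseudocount of 1, 1456 with array quality weights, and 17 when only these 7 arrays entered the fit. In that last fit Hsd17b3, Cyp4f4, Poteml2, Hsd11b1 and Sfn remained called, and 16 other named genes, among them Cpa1 (adjusted p = 0.213), Gja1 (0.113), Kif20a (0.113) and Prm1 (0.183), no longer passed.

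The last step compared adult with immature cells. Tspo rose from 932 ± 345 to 3000 ± 441 (n = 4 each; log2 change 1.76 ± 0.24, adjusted p = 2.2e-05), Cyp11a1 from 2290 ± 357 to 4210 ± 914 and Hsd17b3 from 366 ± 98.6 to 633 ± 148. Star was at 1460 ± 115 in immature and 3150 ± 562 in adult cells. This log2 change of 1.09 ± 0.62 did not pass the test in the fit of all groups (adjusted p = 0.248), and did when only these groups were fitted (adjusted p = 0.000759). Cyp17a1 (0.20 ± 0.22), Insl3 (0.35 ± 0.25), Lhcgr (0.07 ± 0.14) and Pdgfra (-0.13 ± 0.19) did not pass. Among the genes that also rose were Cyp2a1 (22.9 ± 11.2 to 870 ± 299, log2 change 4.48 ± 0.24) and Cyp2a3 (3.74 ± 0.19), cytochrome P450 genes that include a testosterone hydroxylase, the apolipoprotein gene Apoc1 (4.16 ± 0.24) and Urah (3.31 ± 0.17).

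Of 11 testosterone synthesis genes, 5 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.005, and adjusted p = 0.26 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.068). Cholesterol synthesis rose in 6 of 19, or 7 adjusted over the list alone (camera adjusted p = 0.005, and adjusted p = 0.28 with an estimated correlation), with Insig1 at 1.29 ± 0.18 and Fdft1 at 0.56 ± 0.13. Receptors and regulators rose in 6 of 16 and fell in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). The prolactin receptor gene Prlr rose by 1.70 ± 0.31 and Nr0b1 by 1.12 ± 0.14. That call was lost with quantile normalization (adjusted p = 0.10) and without the lowest 40% of probe sets (0.085). Antioxidant enzymes rose in 11 of 33 and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 2.6e-06, and adjusted p = 0.21 with an estimated correlation), among them Mgst2 (279 ± 41.4 to 1390 ± 56.4) and the heme oxygenase gene Hmox1 (1.77 ± 0.16). Of the 22 osteoblast, cartilage and fat genes, 5 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.21 with an estimated correlation), with the chemokine gene Cxcl12 at 1.32 ± 0.24. Immediate early and heat shock genes rose in 3 of 21 and fell in 0, as adjusted over the list alone, with Ier3 at 1.87 ± 0.27. That list passed camera (adjusted p = 0.029), but not with an estimated correlation (adjusted p = 0.60), quantile normalization (0.37) or median centring (0.11).

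Cell cycle genes fell in 32 of 38 cases and rose in 0 (34 and 0 adjusted over the list alone), at a median of -1.58 (camera adjusted p = 7.6e-21, and adjusted p = 0.15 with an estimated correlation). Kif20a went from 181 ± 25.8 to 36.9 ± 4.04 and Prc1 fell by 2.10 on the log2 scale. Matrix genes fell in 21 of 33 and rose in 1, as adjusted over the list alone (median -1.52; camera adjusted p = 1.9e-07, and adjusted p = 0.26 with an estimated correlation). Postn, encoding periostin, went from 460 ± 400 to 12.1 ± 9.28, and Col5a1 from 497 ± 172 to 70.9 ± 32.4. Gli1 (-3.07 ± 0.25), Tcf21 (-1.98 ± 0.25), Igfbp5 (-3.52 ± 0.26) and Sfrp1 (-2.74 ± 0.28) also fell. Cpa1 fell from 523 ± 694 to 4.27 ± 1.98, with a wide immature spread because immature replicate 4 was at 1560.

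Transcripts of other cells moved here too. Hbb and 6 other erythroid and marrow markers of 12 fell and 0 rose, as adjusted over the list alone (camera adjusted p = 0.00075, and adjusted p = 0.24 with an estimated correlation), and the lymphocyte genes Cd7 (-3.62 ± 0.28) and Gzma (-3.63 ± 0.29) also fell. Of 24 leukocyte markers 8 fell, with Tyrobp from 306 ± 84.3 to 68.7 ± 33.1, and 2 rose. Adjusted over the list alone these counts were equal. The list median was 0.21, its mean -0.30, and camera did not call it (adjusted p = 0.72). Endothelial markers rose in 9 of 14, as adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.28 with an estimated correlation). Germ cell markers rose in 6 of 21 and fell in 3 (7 and 3 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.38 with an estimated correlation). The sperm tail gene Odf1 went from 102 ± 29 to 996 ± 629. The germ cell call was lost with a pseudocount of 1 (adjusted p = 0.081), without the lowest 40% of probe sets (0.066), without adult replicate 2 (0.051) and without immature replicate 4 (0.056).

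This step called 2499 probe sets higher and 4048 lower. Of those called, 38.2% were higher as deposited, 48.7% after quantile normalization and 65.2% after median centring, which moved the median of all probe sets by 0.18.

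Over the whole span, adult against stem cells, 6601 probe sets were higher and 6377 lower. Of those called, 50.9% were higher as deposited, 49.3% after quantile normalization and 46.5% after median centring, so neither direction prevailed under all scalings. Cyp17a1 rose by 8.31 ± 0.21. Rises were also called in the carboxylesterase gene Ces1d (7.83 ± 0.24), the peroxisomal oxidase gene Hao2 (7.74 ± 0.21) and Ass1 of the urea cycle (6.15 ± 4.53 in stem, n = 5, to 4640 ± 932 in adult cells, n = 4). Cyp11a1 rose by 7.04 ± 0.15, Insl3 by 7.11 ± 0.24, Lhcgr by 6.36 ± 0.13, Hsd17b3 by 4.41 ± 0.20, Star by 2.31 ± 0.59 and Pdgfra by 1.28 ± 0.18. Falls were called in Postn (-6.46 ± 0.36), Grem1 (-6.16 ± 0.16), the water channel gene Aqp1 (-6.11 ± 0.17) and Il1rl1 (-6.09 ± 0.18).

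Matrix genes fell in 27 of 33 cases and rose in 2, as adjusted over the list alone (median -2.85; camera adjusted p = 3e-11, and adjusted p = 0.18 with an estimated correlation). Cell cycle genes fell in 32 of 38 and rose in 2 (32 and 3 adjusted over the list alone; camera adjusted p = 2.9e-07, and adjusted p = 0.23 with an estimated correlation). Testosterone synthesis genes rose in 9 of 11 and fell in 0, as adjusted over the list alone (median 3.64; camera adjusted p = 4.5e-06, and adjusted p = 0.10 with an estimated correlation). Antioxidant enzymes rose in 20 of 33 and fell in 6 (21 and 6 adjusted over the list alone; camera adjusted p = 0.00089, and adjusted p = 0.25 with an estimated correlation). Gstt2 rose by 3.08 ± 0.14, while the secreted peroxidase gene Gpx3 fell from 1390 ± 365 to 26.8 ± 4.81. Leydig receptors and regulators rose in 13 of 16 and fell in 1, as adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.10 with an estimated correlation), with Nr0b1 at 4.86 ± 0.14. Precursor markers fell in 15 of 25 and rose in 5 (16 and 6 adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.18 with an estimated correlation). Androgen and glucocorticoid metabolism rose in 8 of 17 and fell in 2, as adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.18 with an estimated correlation), with Hsd17b11 at 2.20 ± 0.12; this call was lost with quantile normalization (adjusted p = 0.053). Leukocyte markers stood higher in adult cells in 20 of 24 cases and lower in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 5.8e-06, and adjusted p = 0.31 with an estimated correlation). Germ cell markers stood higher in 15 of 21 and lower in 1, as adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.18 with an estimated correlation). Endothelial markers stood higher in 10 of 14 and lower in 1, as adjusted over the list alone (camera adjusted p = 0.004, and adjusted p = 0.31 with an estimated correlation). Smooth muscle markers stood lower in 11 of 14 (12 adjusted over the list alone; camera adjusted p = 6.2e-06, and adjusted p = 0.18 with an estimated correlation).

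**Figure D3:**
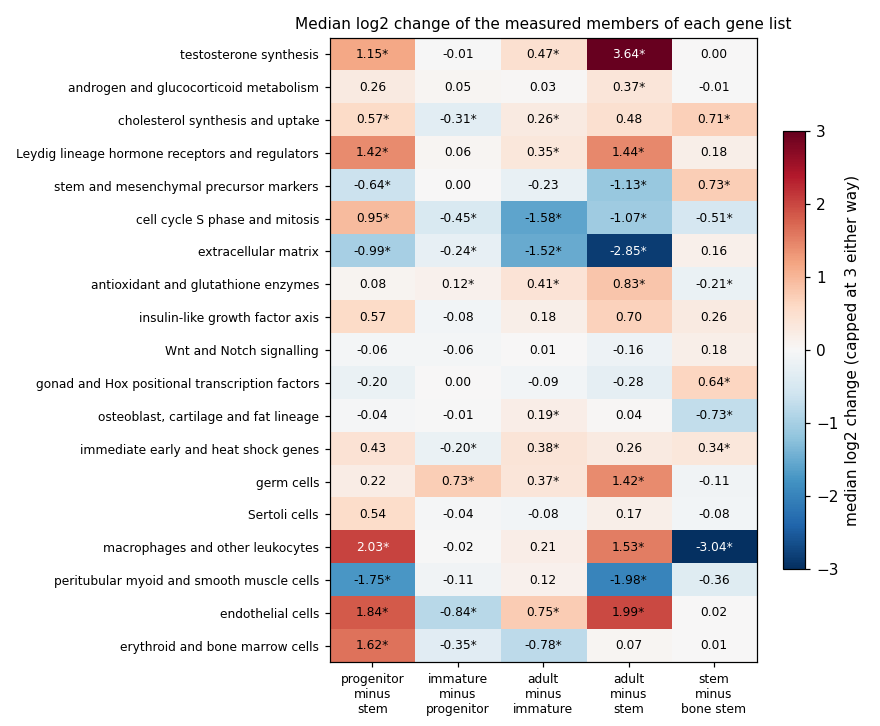
Median log2 change of the measured members of the 19 gene lists (rows) in the 5 comparisons (columns), with colour capped at 3 either way; a star marks a camera adjusted p under the threshold with the preset correlation. Cell cycle genes have medians of 0.95, -0.45 and -1.58 over the 3 steps.

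Stem Leydig cells against bone stem cells set 2 kinds of stem cell side by side, from different tissues. Differences between them include tissue of origin and any difference in isolation or culture. Stem Leydig cells had more of the gonadal regulators Nr5a1 (77.4 ± 10.7, n = 5, against 8.20 ± 3.14, n = 3; log2 change 1.95 ± 0.12, adjusted p = 2.84e-10) and Gata4 (2.85 ± 0.21), the intermediate filament genes Nes (2.60 ± 0.25) and Des (4.76 ± 0.27), the adhesion gene Cdh22 (4.17 ± 0.38), Mfap4 (4.66 ± 0.45) and Olr1 (4.35 ± 0.29). Pdgfra was higher by 0.85 ± 0.20. Bone stem cells had more of the tenascin gene Tnn (2240 ± 515 against 1.81 ± 0.77, log2 change -6.96 ± 0.15), the cartilage proteoglycan gene Acan (-4.78 ± 0.22), Thbs2 (-3.70 ± 0.22) and the bone sialoprotein gene Ibsp (-3.32 ± 0.28).

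Osteoblast, cartilage and fat genes were lower in stem Leydig cells in 12 of 22 cases and higher in 1, as adjusted over the list alone (median -0.73; camera adjusted p = 2.5e-05). This was the one list in the 5 comparisons that also passed with an estimated correlation (adjusted p = 0.032). Gonad and Hox factors were higher in 14 of 28 and lower in 7 (18 and 7 adjusted over the list alone; camera adjusted p = 5e-04, and adjusted p = 0.065 with an estimated correlation). Hoxd10 was at 235 ± 41.7 in stem Leydig and 13.4 ± 5.96 in bone stem cells, while Hoxa9 was at 11.6 ± 1.71 and 175 ± 31.8. Precursor markers were higher in 14 of 25 and lower in 2 (14 and 4 adjusted over the list alone; camera adjusted p = 3e-04, and adjusted p = 0.065 with an estimated correlation), with Nr2f2 at 1.72 ± 0.14. Cholesterol synthesis was higher in 13 of 19 and lower in 1 (14 and 2 adjusted over the list alone; camera adjusted p = 1.4e-07, and adjusted p = 0.065 with an estimated correlation). Cell cycle genes were lower in 16 of 38 and higher in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 1.8e-05, and adjusted p = 0.50 with an estimated correlation). Antioxidant enzymes were lower in 8 of 33 and higher in 2, as adjusted over the list alone, with Hmox1 at -2.06 ± 0.17. Their camera call (adjusted p = 0.035, and adjusted p = 0.66 with an estimated correlation) was lost with quantile normalization (0.18), without bone stem replicate 1 (0.29) and with the replicate number as a block. Immediate early and heat shock genes were higher in 5 of 21 and lower in 0 (7 and 1 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.71 with an estimated correlation). This call was lost with only these groups fitted (adjusted p = 0.056), with the closest pairs averaged (0.064) and with the replicate number as a block. Star was higher by 3.03 ± 0.64, at 740 ± 480 in stem Leydig cells, and in bone stem cells at 441.7 in replicate 1 and 15.9 in replicates 2 and 3.

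Leukocyte markers were far lower in stem Leydig than in bone stem cells, in 17 of 24 cases with 0 higher (18 and 0 adjusted over the list alone; median -3.04; camera adjusted p = 3.2e-18, and adjusted p = 0.065 with an estimated correlation). The macrophage gene Cd68 was at 29.7 ± 10.8 against 2090 ± 233, Tyrobp at 18.1 ± 4.48 against 1990 ± 281, and Laptm5 at 8.44 ± 4.61 against 986 ± 34.1. Whether leukocyte RNA in the bone stem samples carries part of the other differences, the osteoblast, cartilage and fat list among them, was not tested.

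In this comparison 3039 probe sets were higher and 2710 lower in stem Leydig cells. The total of 5749 came to 3752 without bone stem replicate 2, 3746 without bone stem replicate 3, 3674 with the closest pairs averaged and 10996 with array quality weights. The share of called probe sets that were higher was 52.9% as deposited, 48.2% after quantile normalization and 40.7% after median centring.

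**Figure D4:**
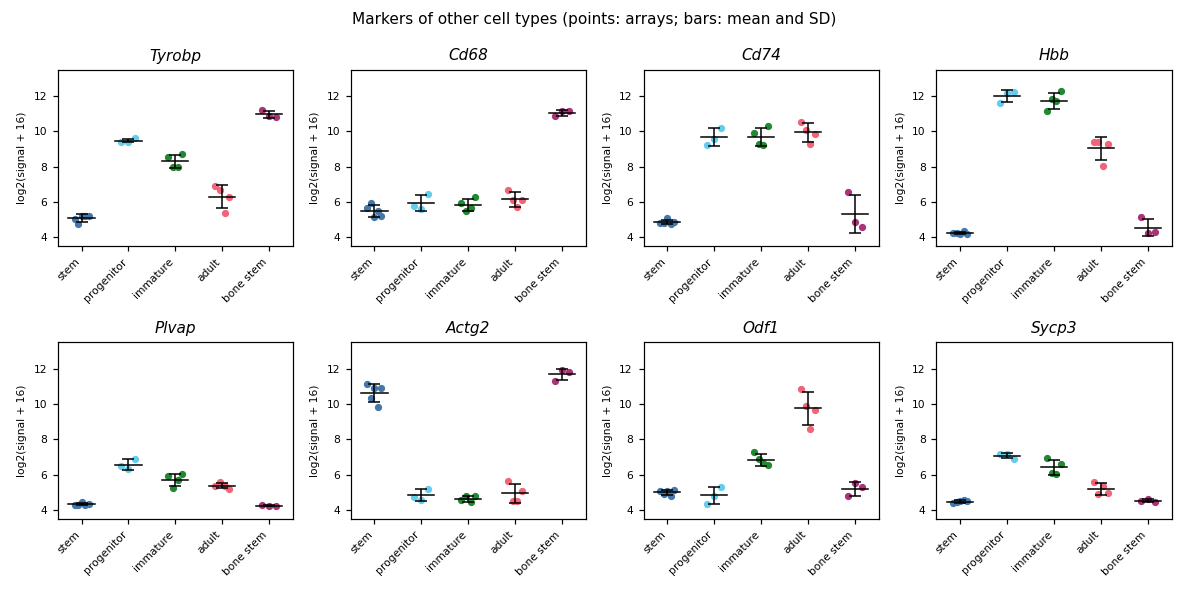
Signal of 8 markers of other cell types in each array, as log2(signal + 16) on the vertical axis, by group; points are arrays, bars the mean and SD. Tyrobp and Cd68 are brightest in bone stem cells, Hbb in progenitor and immature cells, Actg2 in both kinds of stem cell and Odf1 in adult cells.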

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

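The tests of the wrong label of immature replicate 4, of other cells and of germ cells were chosen after the result was seen. The counts over other splits were not. The RNA quality test was recorded as chosen before its result. It was framed around the correlations of immature replicate 4 and the 3' to 5' ratios of progenitor replicate 3, so those had been seen. The splits of the arrays, each into groups of the same sizes, were counted for each comparison. For progenitor against stem 1 of 56 splits, the real one, called as many probe sets (11385, highest other 239). For adult against immature it was 1 of 35 (6547, highest other 720) and for stem against bone stem 1 of 56 (5749, highest other 358). For adult against stem it was 1 of 100 drawn (12978, highest other 9773) and for the 4 stages 1 of 100 drawn (15734, highest other 7087). So no other split counted there called as many. The splits treat each array as a separate sample, so they cannot exclude a chance difference between single animals or cultures. For immature against progenitor 4 of 35 splits called as many (404, highest other 1550), so chance cannot be excluded. The highest was a split that puts immature replicate 4 with the progenitors. Group sizes were kept, so at least 1 progenitor array moved to the immature group in exchange. Its count was several times the real one, which points to a structure of the samples. Moving replicate 4 alone was not counted.

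Immature replicate 4 correlated more with the progenitor arrays than with its own group. Over 1304 probe sets called without it, its median position between the progenitor mean (0) and the immature mean (1) was 0.23. This was within the 0.07 to 0.31 of the progenitor arrays and under the 0.67 to 0.93 of the other immature arrays. The 0.31 was progenitor replicate 3, which itself stood apart, and replicates 1 and 2 were at 0.13 and 0.07, so the overlap rests on replicate 3. A progenitor sample under a wrong label may account for the position. Against that, Hsd17b3 was at 218.4 in this array (35.8 to 74.8 in progenitors, 410.2 to 419.4 in the other immature arrays) and Hsd11b1 at 1598.3 (634.2 to 703.5 in progenitors), genes picked after their values were seen. Its deviation correlated at only 0.04 with that of progenitor replicate 3, the array with the highest actin ratio. This argues against an RNA quality effect shared with that array, but not against lower RNA quality of another kind. In immature replicate 4 the 3' to 5' ratio of Gapdh was 1.524, against 1.134 to 1.177 in the other immature arrays. Its actin ratio was 1.7 (1.539 to 1.695 in the others), and its hexokinase ratio of 2.781 was the lowest of its group. Its low bioB hybridization control (19.2), and a mixed or younger sample, were not tested as reasons and stay open.

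Markers of leukocytes, endothelium and red blood cells were higher in progenitor than in stem arrays. Whether the share of Leydig lineage cells was lower stays open: smooth muscle markers had a median change of -1.75 against 2.03 for leukocytes, but 12 of 14 were at a signal of 100 or more in the stem cells, so their fall does not decide it. Deviations from the group means within the progenitor, immature and adult arrays correlated at a mean of 0.66 among leukocyte markers (95th percentile of 1000 random lists 0.07), 0.41 among endothelial markers (0.15) and 0.26 among erythroid and marrow markers (0.21). RNA of such cells in varying amounts may account for these. For the endothelial and erythroid lists the test does not decide it. Both fell from progenitor to immature arrays, so their members would deviate together on immature replicate 4, which lay near the progenitors. A difference in isolation or culture between the stages is not given in the labels and was not tested.

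Of 8 spermatid transcripts, 5 were called higher in immature than in progenitor arrays and 5 in adult than in immature arrays, with Tnp2 and Odf1 at both steps. Deviations of the 8 within the immature and adult arrays correlated at a mean of 0.58 (95th percentile of random lists 0.25). Spermatid RNA in these samples may account for this, but the test does not decide it. Immature replicate 4, which lay near the progenitors, was among these arrays. Transcripts that differ between immature and progenitor arrays would deviate together on it. Whether germ cells of other stages were present stays open. The meiotic genes Sycp3, Sycp2 and Sycp1 rose in progenitor against stem cells (log2 change 2.60 ± 0.20, 1.10 ± 0.15 and 0.39 ± 0.11). None of them passed the test in immature against progenitor cells. In adult against immature cells Sycp3 (-1.24 ± 0.19) and Sycp2 (-0.74 ± 0.15) fell, while Sycp1 (-0.12 ± 0.11) did not pass. So these genes were not called higher with the spermatid transcripts at either step. A fall alone does not show whether meiotic cells were present. The age of the animals stays open and was not tested.

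Single arrays lay far from the others of their group in 37 of 300 tests, where chance gives about 15. These tests covered adult, immature and stem cells and reuse the same arrays, so they are not independent. The progenitor and bone stem groups, with 3 arrays each, were not tested. In adult cells replicate 3 stood apart in Cxcl12 (2040), Hbb (247), Hsd17b11 (2270), Igf1 (3140), Pdgfra (2150) and Tspo (3670), replicate 2 in Aqp1 (12.8) and Dusp1 (714), and replicate 1 in Prc1 (103). In immature cells replicate 4 stood apart in the 3' to 5' ratio of Gapdh (1.524), the mean log2 of the immediate early list (9.41), Cpa1 (1560), Cyp4f4 (193), Gli1 (346), Hsd17b3 (218), Sfn (134), Sfrp1 (971), Spp1 (15.1) and Tspo (417), and replicate 1 in the hexokinase ratio (18.541), Cyp11a1 (1760), Idi1 (341) and Insl3 (1600). In stem cells replicate 3 stood apart in the actin ratio (1.836), the hexokinase ratio (20.38), the mean log2 of the androgen and glucocorticoid list (6.31), Acan (43.2), Ece1 (142), Igfbp5 (35.2), Nr5a1 (96.3) and Pdgfra (448). Replicate 1 did so in Fosb (113), Laptm5 (16.7), Nes (147) and Sqle (544), and replicate 4 in the mean log2 of the antioxidant list (8.65) and Srd5a3 (286).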

How the results depend on the processing

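Leaving out the 2 arrays standing apart and averaging the 2 closest pairs were chosen after the result was seen. No called gene or list changed direction, but median centring turned the balance of higher and lower probe sets in 4 of the 5 comparisons, all but immature against progenitor. The cause of the differences below was not tested, except that a 2-fold minimum by construction calls fewer. With that minimum, counts (higher and lower) were 4379 (2461 and 1918) for progenitor against stem, 189 (136 and 53) for immature against progenitor, 1796 (659 and 1137) for adult against immature, 5473 (2667 and 2806) for adult against stem and 1902 (975 and 927) for stem against bone stem. Median centring gave 4140 higher and 7938 lower for progenitor against stem, and 4108 and 2191 for adult against immature. Immature against progenitor came to 226 (177 and 49) with a pseudocount of 1, 1456 (851 and 605) with array weights, 17 (16 and 1) with only those groups fitted, 1194 (737 and 457) without the 2 arrays and 157 (118 and 39) with the pairs averaged. Stem against bone stem came to 10996 (6257 and 4739) with array weights and 3674 (1795 higher) with the pairs averaged. Leaving out 1 array gave 9758 to 11091 for progenitor against stem (5674 to 6620 higher, 3955 to 4548 lower), 147 to 1304 for immature against progenitor (102 to 724 and 45 to 580), 5152 to 6652 for adult against immature (2007 to 2445 and 3145 to 4272), 12059 to 12746 for adult against stem (5992 to 6496 and 5831 to 6351), 3746 to 6320 for stem against bone stem (1824 to 3458 and 1922 to 2862) and 14574 to 16444 for the 4 stages. An estimated correlation ended 47 of the 48 list calls; fry made 14 lists pass and 6 miss in one direction, and 40 pass and 2 miss in its mixed form. With the replicate number as a block, all 16 counts stayed within 1.5 times. Cat in immature against progenitor (adjusted p = 0.0791) and the antioxidant (0.056) and immediate early (0.15) lists in stem against bone stem no longer passed. Of 33 pairs of same-numbered arrays, 5 deviated together at over 0.1 (-0.269 to 0.264). Pairs with different numbers were not compared, so whether the numbers pair the samples stays open. Signal over background limits dim genes most, with 29.1% to 47.3% of probe sets under a signal of 16.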

Other observations

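Single genes not described so far also differed along the lineage. Igf1, an insulin-like growth factor gene, rose from 149 ± 60.5 in stem (SD, n = 5) to 2650 ± 328 in adult cells (n = 4), a log2 change of 4.07 ± 0.21, and was also lower in stem Leydig than in bone stem cells (-1.93 ± 0.22). Igfbp6 fell from 1330 ± 104 in immature to 238 ± 134 in adult cells (n = 4 each). Spp1, which encodes osteopontin, fell from 1870 ± 365 in stem to 30.1 ± 6.16 in progenitor cells and rose again to 347 ± 141 in adult cells. The small heat shock protein gene Hspb1 fell by 4.22 on the log2 scale from stem to progenitor cells, while Zfp36 was higher in adult than in stem cells (2.71 ± 0.28).

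Bone stem replicate 1 differed from the other 2 bone stem arrays in the complement gene C1qa, a gene picked after its values were seen, at 1125.8 against 22.4 and 24.2.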
